A study of Mus musculus with 8 samples.

How the data were processed

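RNA of 4 clonal mouse ES cell lines, 2 with a Taf5 knockdown and 2 with a control knockdown, was hybridised against a common pool of parental ES cell RNA on 8 dual-colour arrays, 2 per line with the dyes exchanged. The labels state the group, the line and the dye of every array. Array number 1 of a line carries the sample in Cy3 and number 2 in Cy5. According to the series text each line was grown in duplicate, so the 2 arrays of a line are separate cultures of 1 clone.

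The scanner tables give, per the file headers, the mean pixel intensity of each of 45220 spots in both channels with the median and SD of the local background, and these intensity values were used without further treatment by the authors. The authors' processed matrix holds log2 ratios of sample over parental reference, with array medians of -0.0058 to 0.0080. The background treatment and normalization behind them are not given in the sources used here. The comparison table gives, per the file headers, the authors' log2 difference and a p-value for 7 comparisons of groups or lines. For Taf5-kd against control-kd its log2 differences equal the differences of group means of the processed matrix less a constant, within 1.00e-05. The authors' p-value runs in steps of 0.0002 and lies at 1 for 77.9 to 82.8% of probes. The test behind it, and whether it is adjusted, are not given in the sources used here.

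Of the spots, 41174 are mouse probes and 4046 are controls. The platform annotation gives 1 gene symbol for 34186 mouse probes and none for 6988. Symbols were matched to the RefSeq gene table of assembly GRCm38.p6: those of 30365 probes were current, 3726 were updated through synonyms, and 75 ambiguous and 20 unmatched ones were kept as given. The same table gave the chromosome of each gene and the order of neighbouring genes.

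Values were computed from the scanner tables with limma 3.58.1 in R 4.3.3 (statmod 1.5.0). Plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. The background was corrected by normexp with an offset of 50 and each array was normalized by global loess over the mouse probes, the control spots having weight 0. Nothing was adjusted between arrays. Each array was turned to sample over reference by the dyes in the labels. The log2 ratios before normalization correlated at 0.812 to 0.962 with the authors' processed values across mouse probes with a mean log2 intensity over 9. A spot counted as above background when its signal exceeded the background by 2 background SDs, and probes above background in either channel on at least 4 of 8 arrays were kept, which left 40860 and set aside 314. A gene with several probes was represented by the brightest. This gave 25150 features, 18258 with a symbol and 6892 without. 0 to 5 spots per array reached saturation at 65000.

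The groups were compared with limma's moderated test (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) on all 8 arrays, with a term for dye orientation, which is also a block on the array number, and the line as a random block through duplicateCorrelation (consensus correlation 0.441). The dye term was checked on the data: after removal of line means, arrays of the same number in different lines correlated at 0.700 to 0.829 across features, so the numbers pair the arrays through the dye. Comparisons of single lines gave each line its own mean, with the dye term. Values per group are means and SDs over 4 arrays with the dye term removed. The comparisons, lists, alternative settings and the rule for named genes were fixed before the data were examined, except for the setting without the genes of chromosomes 8 and 11, which was chosen after the chromosome medians had been seen.

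The genes named are Taf5 and those chosen by a rule. For Taf5-kd against control-kd the rule takes the 10 largest rises and 10 largest falls among features past the threshold that moved the same way in all 4 pairings of a Taf5-kd with a control-kd line and carry a symbol that is not a clone or predicted-gene name. It takes 5 and 5 for every other comparison, and up to 4 members per list with the largest change among those past the threshold, or up to 2 with the smallest p where none passed. Other probes of a named gene were looked up and are given where they pass in the opposite direction. The examples chosen for the classes of three-way change were picked from the named genes after their values were seen.

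Over 38 gene lists, covering lineages, pluripotency, signalling, stress, metabolism, the cell cycle, the transcription machinery, imprinting, sex chromosomes and other cell types, limma's camera tested whether members moved further in 1 direction than other genes, with a preset correlation of 0.01 between genes on values whitened for the line correlation, adjusted over the lists. The test was repeated with the correlation estimated from the data, under which 0 of the 12 lists called for Taf5-kd against control-kd passed (7 lists at an unadjusted p under 0.05), nor any in the other comparisons. The estimated correlation was 0.0075 for LIF and STAT3 genes and -0.011 for G1/S genes, under the preset 0.01. Their unadjusted p in this test still rose, from 0.0074 to 0.041 and from 0.0070 to 0.027. A higher correlation between members therefore does not account for every lost call. With the correlation estimated, camera also refers its statistic to the residual degrees of freedom of the arrays, which are few. A call lost in this test, in any comparison, does not by itself show that correlation between genes accounts for the call. Member counts use the adjustment over all features, with the adjustment over the list alone beside it. Some genes stand in several lists, such as Cdx2 in trophectoderm, primitive streak and Wnt targets.

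The procedure was tested on simulated data built on the fitted variances of 25150 features with 200 changed genes. It recovered 60 of 67 genes (89.6%) changed by 0.5 (log2), 66 of 67 (98.5%) changed by 1 and 66 of 66 changed by 2. Of its 390 calls, however, 198 (50.8%) fell on unchanged genes, and 8.11% of the unchanged genes had an unadjusted p under 0.05. The fit on 1 mean per line made 136 calls, 5 of them (3.68%) on unchanged genes, and a fit with fixed line means made 4196 calls, of which 95.3% were on unchanged genes. A single consensus correlation may understate the clone-to-clone variance of many genes, which was not tested. The simulated variance, estimated from 2 lines per group, may overstate it. The random-block fit was kept as the design fixed beforehand and the line-mean counts are printed beside it. In the same data a shifted list was called and 0 of the other lists were. Genes were drawn independently of each other there, so this cannot show how often lists of correlated genes are called falsely. Single-line comparisons recovered 97.8 to 100% of simulated changes of at least 1, and their error leaves out the spread between clones.

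The alternatives tried were no background subtraction and normexp without offset, median centring, scale normalization between arrays, no filter or a filter on all arrays, the mean over probes, no dye term, no line block, line means, fixed line means, eBayes with trend and robust, a 1.7-fold minimum, the authors' processed values, leaving out each array or line, and an estimated correlation for the lists. The number of arrays limits the precision. No batch other than dye orientation is given. Coordinates of genes are not printed, since probe positions are not given in the sources used here.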

Results

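Gene expression was measured on 8 dual-colour long-oligonucleotide arrays in clonal mouse embryonic stem (ES) cell lines with a stable short-hairpin knockdown of Taf5 or a control knockdown. Taf5 is a subunit of TFIID, the general transcription factor that binds core promoters. The lines were derived from IB10 ES cells, a subclone of E14, by lentiviral transduction, puromycin selection and colony picking, and were grown in medium with LIF on gelatin. There were 2 Taf5-kd lines and 2 control-kd lines, each on 2 arrays with opposite dyes, giving 4 arrays per group. Every array carried RNA of 1 line against a common pool of parental ES cell RNA, so all values are log2 ratios to that parental reference. The median signal of the sample channel, before background correction, lay between 123 and 186 intensity units per array, with a median background of 35 to 39.5. In that channel 90.9 to 98.7% of the mouse probes stood above background. After filtering, 25150 features were tested, 18258 of them with a gene symbol. Across these features, with the dye effect removed, the arrays of a line correlated at 0.946 to 0.970, lines of a group at 0.741 to 0.834 and arrays of different groups at 0.166 to 0.487. Genes are not independent replicates. The number of lines, 2 per group, limits the precision of every group comparison.

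Taf5, the targeted gene on chromosome 19 (probe MMAB025743), was 2.65-fold lower in the Taf5-kd lines than in the control-kd lines, a log2 fold change of -1.40 ± 0.10 (SE; adjusted p = 1.08e-04). Its log2 ratio to the parental reference was 0.31 ± 0.20 (SD, n = 4 arrays) in control-kd cells and -1.10 ± 0.04 (SD, n = 4) in Taf5-kd cells. The other 2 probes of Taf5 gave -1.48 and -1.51, and the authors' own values for the 3 probes ran from -1.66 to -1.52. Against the controls, Taf5 stood at -1.39 in Taf5-kd line 1 and at -1.42 in line 2. The control-kd lines themselves lay 0.31 ± 0.07 (SE) above the parental reference (unadjusted p = 0.00221, past the threshold), a difference that did not pass with 1 mean per line (adjusted p = 0.0926). The 2 arrays of control-kd line 1 stood at 0.44 and 0.51 and those of control-kd line 2 at 0.14 each. The fold change of Taf5 was -1.24 without control-kd line 1 and -1.57 without control-kd line 2.

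The comparison of Taf5-kd with control-kd lines was made to look for transcripts that depend on this TFIID subunit in ES cells. A difference between the groups can also come from a departure of the control-kd lines from the parental level. Imprinted genes were among the strongest rises. Mest, a paternally expressed gene of the hydrolase family, rose by 4.01 ± 1.10 (log2, SE; 16.1-fold), Plagl1, an imprinted zinc finger factor, by 3.84 ± 0.14 and Igf2, the insulin-like growth factor, by 2.91 ± 0.26. Brachyury (T), the transcription factor of the primitive streak, rose by 3.18 ± 0.76, and Dppa3, a maternal factor also expressed in naive ES cells, by 3.13 ± 0.40. Anxa3, an annexin, rose by 3.15 ± 0.16, the serine protease gene Prss23 by 2.80 ± 0.25, the zinc transporter gene Slc39a8 by 2.77 ± 0.33, Igfbp3, which codes for an IGF-binding protein, by 2.74 ± 0.57, and Gbp2, an interferon-inducible GTPase gene, by 2.74 ± 0.45. In the control-kd lines most of these genes lay far under the parental level, for example Prss23 at -4.15 ± 0.35 (SD, n = 4) and Anxa3 at -3.70 ± 0.06. Plagl1 lay at -1.53 ± 0.19 in control-kd, where 3 of 4 arrays detected it above background, and at 2.31 ± 0.16 in Taf5-kd. The size of its rise rests in part on a signal near background and is not exact.

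Among the falls, Khdc3, a gene of the oocyte's maternal complex, fell by 2.48 ± 0.41 (log2, SE) and Tbx3, a transcription factor of naive pluripotency, changed by -2.27 ± 0.19 (4.83-fold). Atf4, the transcription factor of the amino acid stress response, fell by 2.02 ± 0.18, from 0.27 ± 0.28 (SD, n = 4) in control-kd to -1.76 ± 0.30 in Taf5-kd. Rpl39l, a paralog of a ribosomal protein gene, fell by 2.24 ± 0.18, as did the trypsin inhibitor gene Spink1 (-2.20 ± 0.15), Aard (-2.13 ± 0.44), Lrrc2 (-2.12 ± 0.11) and the metal ion transporter gene Slc11a1 (-2.08 ± 0.17). The alpha-defensin gene Defa3 fell by 2.02 ± 0.20, and Mymx, known from myoblast fusion, fell by 2.01 ± 0.19. Defa3 was above background on 3 of 4 Taf5-kd arrays, so its fall is not exact. Tbx3, Rpl39l, Aard, Defa3 and Mymx lay above the parental level in control-kd cells, at 1.93 ± 0.14, 1.85 ± 0.20, 1.74 ± 0.09, 1.39 ± 0.42 and 1.62 ± 0.15.

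**Figure D1:**
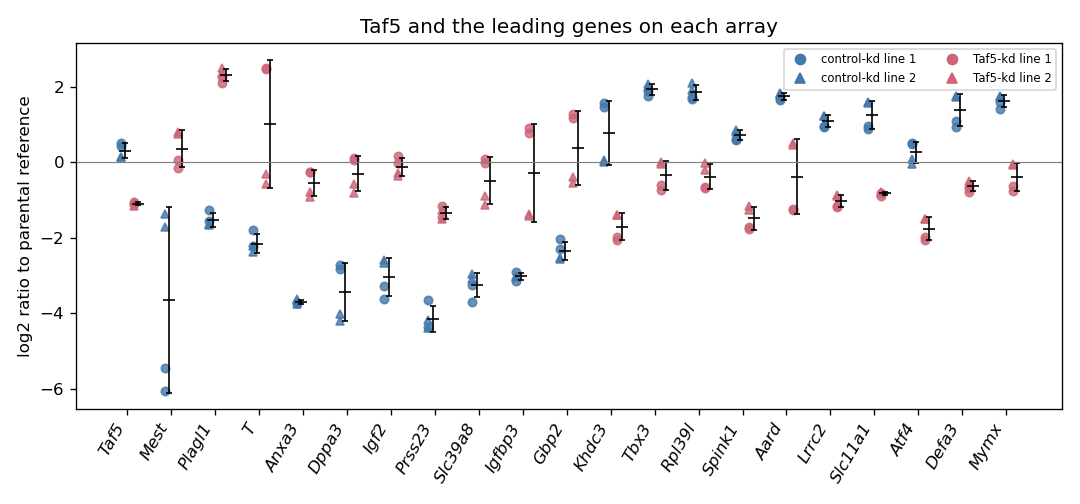
Log2 ratio to the parental reference (vertical axis) of Taf5 and of the 10 genes that rose and the 10 that fell most, on each array with the dye term removed (points, 4 per group; circles line 1, triangles line 2), with the mean and SD of the 4 arrays of a group (black bars). The control-kd arrays of Mest spread widely (mean -3.65, SD 2.45) and the Taf5-kd arrays of T fall apart by line (mean 1.02), while Plagl1 and Taf5 show little spread.

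By the rule that chose them, each of these 20 leading genes moved the same way in all 4 pairings of a Taf5-kd line with a control-kd line. With 1 mean per line in place of the arrays, 7 of them missed the threshold, namely Mest (adjusted p = 0.215), T (0.170), Dppa3 (0.0585), Igfbp3 (0.137), Gbp2 (0.0892), Khdc3 (0.0916) and Aard (0.136). The call of Mest (adjusted p = 0.0340) was also lost on leaving out any 1 of 6 arrays: 3.44 without control-kd replicate 1 and 3.87 without replicate 2, and 4.04, 4.16, 3.92 and 3.95 without Taf5-kd replicates 1, 2, 3 and 4, at adjusted p from 0.0566 to 0.0824. The size of its rise rests on the control-kd lines, which lay at -5.76 and -1.54: it was 1.90 ± 0.30 without control-kd line 1 and 6.12 ± 0.36 without line 2, and the authors' p for Mest is 0.655. Without Taf5-kd line 1, T stood at 1.71, Igfbp3 at 1.62 and Aard at -1.27.

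In total 5673 of 25150 features passed the threshold, 3114 higher and 2559 lower in Taf5-kd, and 923 of them differed at least 1.7-fold (573 higher, 350 lower). With 1 mean per line the count was 1950 (1133 higher, 817 lower), of which 1933 were also among the 5673. In simulated data with clone-to-clone differences and 200 of 25150 genes changed, the model used for the 5673 made 50.8% of its calls on unchanged genes (198 of 390) and the line-mean model 3.68% (5 of 136). These shares depend on how many genes are changed and are not estimates for the 5673. Under median centring in place of loess normalization, 533 features passed.

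The gene lists fixed beforehand that were higher in Taf5-kd were led by actin cytoskeleton and SRF targets. Of 28 measured members 21 rose and 2 fell (21 and 2 adjusted over the list alone; 15 and 0 with line means), with a median of 0.92 (log2) and adjusted p = 3.1e-11. Beside Anxa3, Tpm1 rose by 2.38 ± 0.16 (SE) and Tpm4 by 1.79 ± 0.14, both tropomyosin genes, and Ccn1, a matricellular SRF and YAP target, by 1.96 ± 0.18. With an estimated correlation between genes the list's adjusted p = 0.208. Imprinted genes rose in 10 of 23 and fell in 2 (11 and 3 adjusted over the list alone; 5 and 0 with line means; adjusted p = 2.55e-04), and Nnat joined Mest, Plagl1 and Igf2 with a rise of 1.95 ± 0.27. The list's adjusted p = 0.208 with an estimated correlation. Trophectoderm and placenta genes rose in 8 of 20 with no falls (10 rises and 2 falls adjusted over the list alone; 4 and 0 with line means; adjusted p = 0.00480). Cdx2, the trophectoderm and posterior patterning factor, rose by 2.61 ± 0.26, the keratin genes Krt18 and Krt8 by 2.60 ± 0.41 and 1.89 ± 0.42, and Id2, an inhibitor of basic helix-loop-helix factors, by 2.23 ± 0.12. This list had adjusted p = 0.366 with an estimated correlation. Early-response genes of FGF and ERK signalling rose in 11 of 25 and fell in 2 (12 and 3 adjusted over the list alone; 5 and 0 with line means; adjusted p = 0.00669). Dusp4, a MAP kinase phosphatase gene, rose by 2.22 ± 0.42 and Jun by 1.23 ± 0.17, and Ccn2 rose 3.25-fold. The list had adjusted p = 0.273 with an estimated correlation and 0.117 without control-kd line 1.

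Naive and core pluripotency genes were lower. Of 31 measured members 20 fell and 2 rose (25 and 2 adjusted over the list alone; 7 and 0 with line means), with a median of -0.52 and adjusted p = 4.39e-09. Nr0b1 fell by 1.82 ± 0.24 (SE) and Tet2, a DNA demethylation enzyme gene, fell by 1.64 ± 0.19, together with Tbx3. Dppa3 went the other way. The list had adjusted p = 0.223 with an estimated correlation. LIF and STAT3 response genes fell in 7 of 19 and rose in 3 (9 and 4 adjusted over the list alone; 3 and 0 with line means; adjusted p = 0.0255). Klf4 and Klf5, pluripotency factors downstream of LIF, stood at -1.21 ± 0.08 and -1.13 ± 0.08 and Icam1 at -1.32 ± 0.13, and Fos rose by 1.15 ± 0.29. This list had adjusted p = 0.223 with an estimated correlation, 0.0746 without control-kd line 1 and 0.0725 without Taf5-kd line 1. Its call was also lost with line means (0.0895) and without the line block (0.0611), in 6 of 25 settings in all.

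Some metabolic and growth lists were lower as well, while oxidative phosphorylation, ribosome biogenesis and cholesterol biosynthesis gave no call in the setting used. Amino acid and ATF4 stress genes fell in 11 of 24 and rose in 1 (15 and 1 adjusted over the list alone; 5 and 0 with line means; adjusted p = 1.39e-04), among them Cth (-1.55 ± 0.16), Nupr1 (-1.43 ± 0.15) and Trib3 (-1.37 ± 0.13). Its adjusted p = 0.208 with an estimated correlation. Glycolysis and hypoxia genes fell in 14 of 29 and rose in 3 (17 and 4 adjusted over the list alone; 8 and 1 with line means; adjusted p = 1.29e-04), including Bnip3 (-1.13 ± 0.15), the phosphofructokinase gene Pfkp (-1.02 ± 0.13) and Pdk1 (-0.95 ± 0.08). The adjusted p = 0.208 with an estimated correlation. Cytosolic ribosomal protein genes fell in 17 of 41 and rose in 1 (18 and 1 adjusted over the list alone; 8 and 1 with line means; adjusted p = 1.61e-05), by small amounts such as -0.65 ± 0.08 for Rpl13a and -0.60 ± 0.08 for Rps21. Their adjusted p = 0.359 with an estimated correlation. Genes of the G1/S transition and replication fell in 12 of 32 and rose in 5 (14 and 6 adjusted over the list alone; 4 and 1 with line means; adjusted p = 0.0255). Ccnd3, a D-type cyclin gene, fell by 0.73 ± 0.10 and Mcm3, of the replicative helicase, fell by 0.69 ± 0.08. The list had adjusted p = 0.208 with an estimated correlation and 0.0582 without Taf5-kd line 2. G2/M genes fell in 9 of 27 and rose in 4 (the same counts adjusted over the list alone; 3 and 2 with line means; adjusted p = 0.0440), with Bub1b of the spindle checkpoint at -0.76 ± 0.11. The list had adjusted p = 0.518 with an estimated correlation. Leaving out control-kd replicate 1, control-kd replicate 2 or Taf5-kd replicate 2 gave it 0.0534, 0.0631 and 0.0740, and leaving out control-kd line 1 or Taf5-kd line 1 gave 0.346 and 0.0999. Its call was also lost with line means (0.108) and without the line block (0.0805), in 11 of 25 settings in all.

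Mediator subunit genes rose in 12 of 31 and fell in 3 (15 and 4 adjusted over the list alone; 5 and 0 with line means; adjusted p = 0.0255), led by Med9 at 0.66 ± 0.04 (SE) and Med14 at 0.61 ± 0.07. The list had adjusted p = 0.273 with an estimated correlation and 0.0773 without control-kd line 1, and 0.263 under median centring. Its call was lost in 7 of 25 settings in all. Of its members 8 lie on chromosomes 8 and 11, Med9, Med26 and Med31 among them, and without the genes of those chromosomes the list's median was 0.0066 (adjusted p = 0.449). Genes of these 2 chromosomes stood apart as a whole. Over the genes brighter than the median gene, the median log2 ratio to the parental reference on chromosome 8 was -0.14 and -0.13 in the control-kd lines and 0.14 and 0.14 in the Taf5-kd lines, and on chromosome 11 it was -0.14 and -0.13 against 0.08 and 0.09. Of 2335 tested genes there 898 were higher and 84 lower in Taf5-kd. Without them 4606 features passed, 2177 higher and 2429 lower, where the full count holds more rises than falls. This setting was chosen after the chromosome medians were seen.

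**Figure D2:**
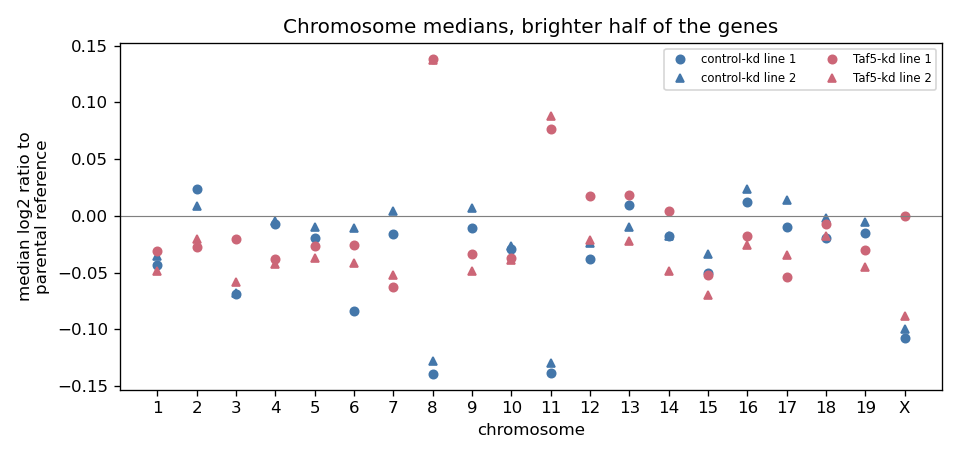
Median log2 ratio to the parental reference (vertical axis) of the genes brighter than the median gene on each chromosome (horizontal axis), for each of the 4 lines (circles line 1, triangles line 2; mean of 2 arrays per line). On chromosomes 8 and 11 both control-kd lines lie between -0.14 and -0.13 and the Taf5-kd lines between 0.08 and 0.14.

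Among the lists without a call, primed epiblast genes came nearest, with 7 of 17 higher and 2 lower on either adjustment (adjusted over the list alone 7 and 2, with line means 3 and 2; adjusted p = 0.0596), including Cdh2 at 1.64 ± 0.09 and Otx2 at 1.60 ± 0.42 (SE). The list passed without control-kd replicate 3 or 4 (0.0406, 0.0494), without Taf5-kd replicate 3 or 4 (0.0477, 0.0417) and without the genes of chromosomes 8 and 11 (0.0144). It passed in 12 of 25 settings, among them median centring (0.00192), the authors' processed values (0.0444), no background subtraction (0.0370), and without Taf5-kd line 2 (0.0160) or control-kd line 2 (0.00601). Primitive streak genes had 3 of 19 higher (T, Cdx2 and Wnt3, the last at 1.89 ± 0.43) and none lower on either adjustment (1 and 0 with line means, adjusted p = 0.0725; 0.0359 and 0.0476 without Taf5-kd replicates 3 and 4, 6.94e-04 without Taf5-kd line 2, and a call in 8 of 25 settings). Wnt targets had 7 of 19 higher and 2 lower (8 and 3 adjusted over the list alone, 2 and 2 with line means; adjusted p = 0.0755; 0.0477 and 0.0476 without the same arrays, 0.00416 without Taf5-kd line 2, and a call in 8 of 25 settings), with Sp5 at 2.50 ± 0.53. Primitive endoderm genes had 4 of 23 lower on either adjustment, among them Lama1 at -1.60 ± 0.30 and Apoe at -1.27 ± 0.11 (2 lower with line means, adjusted p = 0.0773). The list passed without control-kd replicate 1 (0.0282). Its median of -0.21 was -0.71 without control-kd line 1 (adjusted p = 3.17e-08) and 0.16 without control-kd line 2 (adjusted p = 0.134), and it passed under median centring (0.00546). Interferon response genes had 8 of 28 higher and 4 lower (11 and 4 adjusted over the list alone, 1 and 2 with line means; adjusted p = 0.0921; 0.0314 without Taf5-kd replicate 4), with Irf1 at 2.10 ± 0.32 and B2m at 1.31 ± 0.19. The interferon median of 0.096 was 0.19 without Taf5-kd line 2 (adjusted p = 4.34e-04), and the list passed under median centring (0.0111). Ddx58 was lower on 1 probe (-0.56) and higher on another (0.38). Genes of the unfolded protein response had 2 of 21 higher and 5 lower (2 and 6 adjusted over the list alone, 1 and 1 with line means; adjusted p = 0.0872; 0.0282 without control-kd replicate 1). The median of this list was -0.19, and -0.35 without control-kd line 1 (adjusted p = 1.27e-04), and it passed under median centring (0.0113). Nodal, BMP and TGF-beta response genes had 4 of 17 higher and 2 lower on either adjustment (3 and 1 with line means, adjusted p = 0.0773; 0.0311 without the genes of chromosomes 8 and 11 and 0.0424 without control-kd line 1).

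Subunits of TFIID other than Taf5 gave 3 of 16 higher and 5 lower (4 and 6 adjusted over the list alone; 0 and 0 with line means), with no call (adjusted p = 0.946). Taf13 stood at -0.57 ± 0.16, Taf1 at -0.49 ± 0.12, Taf7 at -0.41 ± 0.06 and Taf15 at 0.34 ± 0.08 (log2, SE), and the list's median (0.073) and its mean (-0.036) and test differed in sign. SAGA and ATAC subunits, listed without those shared with TFIID, had 7 of 24 higher and 2 lower (8 and 3 adjusted over the list alone, 3 and 2 with line means; adjusted p = 0.208), with Kat2b at -0.80 ± 0.09 and Tada1 at 0.61 ± 0.06. RNA polymerase II and general factor genes had 8 of 31 higher and 2 lower on either adjustment (6 and 1 with line means, adjusted p = 0.208), with Polr2c at 0.92 ± 0.07, a gene of chromosome 8, and Gtf2h1 at -0.88 ± 0.08. Polycomb subunits had 4 of 28 higher and 7 lower (4 and 8 adjusted over the list alone, 3 and 2 with line means; adjusted p = 0.708), with Eed at -0.91 ± 0.09 and Suz12, on chromosome 11, at 0.78 ± 0.06.

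The remaining lists gave no call in the setting used. Under median centring neuroectoderm passed (median 0.055, adjusted p = 0.0356). So did X-linked genes (adjusted p = 0.0101), ribosome biogenesis and Myc targets (adjusted p = 0.0111) and oxidative phosphorylation (adjusted p = 0.0182), each with a median of -0.14. Higher and lower members numbered 4 and 2 of 24 for mesoderm, muscle and heart (adjusted p = 0.396), 5 and 1 of 24 for neuroectoderm (0.152; Nefm at 2.02 ± 0.40, SE), 2 and 5 of 23 for germ cell genes (0.708; Dnmt3l at -1.63 ± 0.10), and 0 and 1 of 10 for two-cell-like genes (0.336), the same when adjusted over the list alone. They numbered 5 and 6 of 26 for p53 targets (0.328; 5 and 7 adjusted over the list alone), 4 and 2 of 19 for apoptosis genes (0.809; 5 and 3), 6 and 3 of 17 for heat shock proteins (0.615; 6 and 3), 4 and 5 of 23 for NRF2 targets (0.809; 7 and 7) and 4 and 7 of 35 for oxidative phosphorylation (0.615; 4 and 7). For ribosome biogenesis and Myc targets they were 4 and 7 of 30 (0.396; 6 and 8 adjusted over the list alone), for cholesterol biosynthesis 2 and 0 of 22 (0.533; 2 and 0; called higher without control-kd line 1, adjusted p = 2.12e-04, and lower without control-kd line 2, adjusted p = 0.0391), and for X-linked genes 1 and 5 of 16 (0.168; 1 and 5). Y-linked genes had 0 of 7 past the threshold (adjusted p = 0.336; 0.0277 without control-kd line 1), Eif2s3y standing at 2.63 ± 1.28. This rests on control-kd line 2, where Eif2s3y lay at -4.73 beside 0.37 in control-kd line 1. Its signal was above background on 3 of 4 control-kd arrays. Lists of markers of other cell types gave no call in the setting used: fibroblast and matrix genes had 8 of 26 higher and 2 lower (0.139; 0.0463 without background subtraction and 0.0110 under median centring, where the list passed; 8 and 4 adjusted over the list alone; Col1a1 at 1.74 ± 0.38, Vim at 1.02 ± 0.12) and blood and immune genes 0 higher and 3 of 22 lower (0.164; 0 and 3; Laptm5 at -1.85 ± 0.17, Cd68 at -1.45 ± 0.11). With line means the higher and lower members numbered 2 and 1 for mesoderm, 2 and 0 for neuroectoderm, 1 and 2 for germ cell genes, 0 and 1 for two-cell-like genes, 1 and 2 for p53 targets, and 2 and 1 each for apoptosis genes and heat shock proteins. These counts were 2 and 2 for NRF2 targets, 0 and 2 for oxidative phosphorylation, 1 and 3 for ribosome biogenesis, and 0 and 3 for X-linked genes. They were 4 and 0 for fibroblast and matrix genes, 0 and 2 for blood and immune genes, and 0 and 0 for cholesterol biosynthesis and Y-linked genes. The median and mean differed in sign for germ cell genes (0.055 and -0.091), NRF2 targets (0.019 and -0.080) and cholesterol biosynthesis (-0.030 and 0.088), the test following the mean. Of the named members, Utp20 was lower on the probe used (-0.46) and higher on another (0.17).

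The control-kd lines were compared with the parental reference to see what transduction, selection and cloning with a control hairpin go along with. Prss23 fell by 4.15 ± 0.18 (log2, SE; 17.7-fold), as did the keratin gene Krt18 (-3.98 ± 0.29), Anxa3 (-3.70 ± 0.11), Mest (-3.65 ± 0.78) and Dppa3 (-3.43 ± 0.28). The largest rises were those of Tbx3 (1.93 ± 0.13), Rpl39l (1.85 ± 0.13), Cobl, an actin nucleator gene (1.84 ± 0.11), Ankrd33b (1.79 ± 0.18) and Aard (1.74 ± 0.31). Actin and SRF genes fell in 24 of 28 and rose in 1 (24 and 1 adjusted over the list alone, 24 and 0 with line means), with a median of -1.43 and adjusted p = 7.4e-17. Thbs1, the thrombospondin gene, fell by 2.94 ± 0.14 and Tpm1 fell by 2.52 ± 0.11. Its adjusted p = 0.123 with an estimated correlation. The unfolded protein response fell in 17 of 21 with no rises on either adjustment (15 and 0 with line means, adjusted p = 1.88e-09), with the chaperone genes Canx, on chromosome 11, and Hsp90b1 at -1.14 ± 0.06 and -0.88 ± 0.08. With an estimated correlation its adjusted p = 0.394.

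Imprinted genes fell in 14 of 23 and rose in 1 against the parental reference (15 and 1 adjusted over the list alone, 9 and 0 with line means; adjusted p = 4.59e-05, and adjusted p = 0.123 with an estimated correlation), with Igf2 at -3.04 ± 0.18 (SE) and Nnat at -1.82 ± 0.19. Trophectoderm genes fell in 12 of 20 on either adjustment (9 with line means, adjusted p = 1.08e-04, and adjusted p = 0.388 with an estimated correlation), with Krt8 at -3.37 ± 0.29 and Id2 at -2.25 ± 0.08. Nodal, BMP and TGF-beta response genes fell in 8 of 17 and rose in 2 (12 and 3 adjusted over the list alone, 6 and 1 with line means; adjusted p = 0.00817, and adjusted p = 0.162 with an estimated correlation), with the Nodal targets Lefty1 and Lefty2 at -2.23 ± 0.28 and -1.51 ± 0.15. Fibroblast and matrix genes fell in 15 of 26 and rose in 2 on either adjustment (12 and 2 with line means, adjusted p = 0.00240, and adjusted p = 0.206 with an estimated correlation), with Col1a1 at -3.09 ± 0.27. Naive pluripotency genes rose in 20 of 31 and fell in 6 (22 and 7 adjusted over the list alone, 10 and 3 with line means; adjusted p = 6.66e-04, and adjusted p = 0.517 with an estimated correlation), with Gbx2 at 1.72 ± 0.30 and Nr0b1 at 1.42 ± 0.17. G1/S genes rose in 18 of 32 and fell in 4 (18 and 6 adjusted over the list alone, 14 and 1 with line means; adjusted p = 0.00205, and adjusted p = 0.123 with an estimated correlation), and G2/M genes rose in 14 of 27 and fell in 1 (15 and 1 adjusted over the list alone, 10 and 1 with line means; adjusted p = 6.66e-04, and adjusted p = 0.494 with an estimated correlation). TFIID subunits other than Taf5 rose in 6 of 16 with no falls on either adjustment (5 and 0 with line means, adjusted p = 0.00216, and adjusted p = 0.125 with an estimated correlation), Taf13 by 0.70 ± 0.11 and Taf7 by 0.59 ± 0.05. In all, 8243 features passed (3520 higher, 4723 lower), 5378 with line means and 2118 under median centring, and 969 differed at least 1.7-fold, 812 of them lower. The reference was 1 pool without replication, so its own spread is not part of these errors.

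In the Taf5-kd lines, compared with the same reference, Plagl1 rose by 2.31 ± 0.10 (log2, SE; 4.96-fold), Cdx2 by 1.82 ± 0.19, Hoxb8, a posterior homeobox gene on chromosome 11, by 1.49 ± 0.11, the neurofilament gene Nefm by 1.42 ± 0.29 and Acot1 by 1.39 ± 0.09. Sfmbt2, an imprinted gene of the Polycomb family, fell by 2.07 ± 0.04, as did Ifitm3 (-1.88 ± 0.18), Spp1 (-1.86 ± 0.19), the basement membrane gene Nid1 (-1.85 ± 0.12) and Klhl13 (-1.82 ± 0.28). The unfolded protein response fell in 20 of 21 (21 adjusted over the list alone, 17 with line means) with a median of -0.73 and adjusted p = 4.5e-13. Hspa5, the chaperone BiP, fell by 1.18 ± 0.12. With an estimated correlation its adjusted p = 0.248. Cytosolic ribosomal protein genes fell in 24 of 41 and rose in 2 (25 and 2 adjusted over the list alone, 18 and 1 with line means; adjusted p = 2.93e-06, and adjusted p = 0.298 with an estimated correlation), with Rpl9 and Rps28 at -1.17 ± 0.06 and -1.16 ± 0.04. ATF4 stress genes fell in 15 of 24 with no rises (16 and 0 adjusted over the list alone, 8 and 0 with line means; adjusted p = 1.01e-05, and adjusted p = 0.248 with an estimated correlation), with Atf4 at -1.76 ± 0.13 and the amino acid transporter gene Slc7a3 at -1.26 ± 0.07. Actin and SRF genes fell in 18 of 28 and rose in 1 on either adjustment (11 and 1 with line means, adjusted p = 1.65e-05, and adjusted p = 0.274 with an estimated correlation), with a median of -0.42 beside -1.43 in control-kd.

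Naive pluripotency genes fell in 13 of 31 with no rises in Taf5-kd against the parental reference (15 and 2 adjusted over the list alone, 7 and 0 with line means; adjusted p = 0.00328, and adjusted p = 0.509 with an estimated correlation), with Gdf3 at -1.22 ± 0.08 (SE). Glycolysis genes fell in 15 of 29 and rose in 2 (17 and 4 adjusted over the list alone, 9 and 0 with line means; adjusted p = 0.00464, and adjusted p = 0.248 with an estimated correlation), the glucose transporter gene Slc2a3 among them (-1.11 ± 0.09). LIF and STAT3 genes fell in 9 of 19 and rose in 1 on either adjustment (3 and 0 with line means, adjusted p = 0.0445). X-linked genes fell in 9 of 16 and rose in 3 (10 and 3 adjusted over the list alone, 5 and 2 with line means; adjusted p = 0.0362). Both lists had adjusted p = 0.248 with an estimated correlation. Lists of the transcription machinery were higher: TFIID subunits other than Taf5 rose in 8 of 16 and fell in 3 on either adjustment (7 and 2 with line means, adjusted p = 0.00995), RNA polymerase II and general factors rose in 12 of 31 and fell in 4 (14 and 5 adjusted over the list alone, 11 and 1 with line means; adjusted p = 0.00611) and Mediator subunits rose in 12 of 31 and fell in 2 (15 and 2 adjusted over the list alone, 5 and 1 with line means; adjusted p = 0.00555), each with adjusted p = 0.248 with an estimated correlation. Examples were Taf12 at 0.63 ± 0.05, Gtf2a1 at 0.68 ± 0.09 and Med26, on chromosome 8, at 0.55 ± 0.07. The TFIID list was also higher in control-kd against parental (adjusted p = 0.00216) and did not differ between the groups (adjusted p = 0.946). Taf12 lay at 0.37 and 0.40 on the arrays of control-kd line 1 and at 0.61 on those of line 2. Of the Mediator members 8 lie on chromosomes 8 and 11, and the lists of this comparison were not tested without those genes. In all, 7853 features passed (3528 higher, 4325 lower), 4631 with line means and 1072 under median centring. 504 differed at least 1.7-fold, 437 of them lower.

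**Figure D3:**
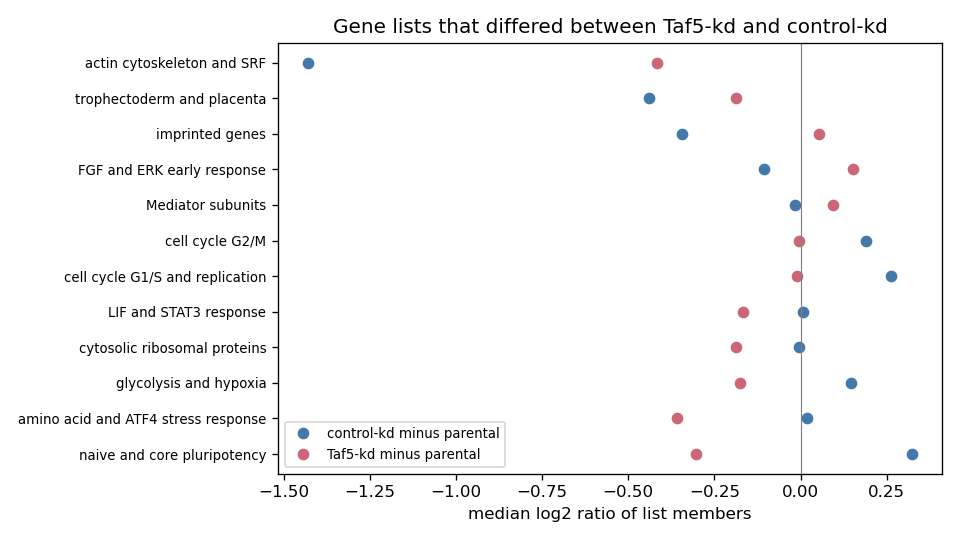
Median log2 ratio to the parental reference over the measured members (horizontal axis) of the 12 gene lists that differed between Taf5-kd and control-kd lines, in control-kd (blue) and Taf5-kd (red) cells. Actin and SRF genes lie at -1.43 in control-kd and -0.42 in Taf5-kd, naive pluripotency genes at 0.32 and -0.30.

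Set against the parental level, the 5673 features that differed between Taf5-kd and control-kd fell into 5 classes. For 1945 (34.3%), Igf2 and Tpm1 among them, control-kd differed from parental the opposite way and Taf5-kd did not pass. For 1665 (29.3%), Atf4 among them, Taf5-kd differed from parental the same way and control-kd did not pass. Both groups differed from parental in opposite directions for 1039 (18.3%), as Plagl1 and Taf5 did, and in the same direction for 855 (15.1%), as Anxa3 and Prss23 did. Neither passed for 169 (2.98%). Over all features 4533 passed in both groups against parental, 3494 of them in the same direction. The same parental pool enters both contrasts, which by itself gives calls in the same direction, and no count for unchanged groups was computed.

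Each Taf5-kd line was also compared with the 4 control-kd arrays. In line 1, T rose by 4.64 ± 0.12 (log2, SE), Igfbp3 by 3.87 ± 0.07, Plagl1 by 3.72 ± 0.08, Gbp2b by 3.60 ± 0.05 and Mest by 3.60 ± 0.16, while falls were seen for Aard (-2.99 ± 0.04), Khdc3 (-2.79 ± 0.04), Tbx3 (-2.60 ± 0.06), Rpl39l (-2.51 ± 0.07) and the adenylate kinase gene Ak7 (-2.51 ± 0.05). In line 2, Mest rose by 4.42 ± 0.16, Plagl1 by 3.97 ± 0.08, Anxa3 by 2.85 ± 0.05, Prss23 by 2.77 ± 0.18 and Dppa3 by 2.74 ± 0.08, while falls were seen for the imprinted gene Grb10 (-2.26 ± 0.04), Khdc3 (-2.17 ± 0.04), Slc11a1 (-2.06 ± 0.04), Lrrc2 (-1.98 ± 0.04) and Rpl39l (-1.96 ± 0.07). Naive pluripotency genes fell in 28 of 31 in line 1 (28 adjusted over the list alone; adjusted p = 1.77e-12) and in 24 of 31 in line 2 (25 adjusted over the list alone; adjusted p = 1.61e-07). Actin and SRF genes rose in 22 of 28 in each line (23 and 22 adjusted over the list alone; adjusted p = 2.14e-10 and 6.62e-11). Interferon genes passed as a list in line 1, with 17 of 28 higher and 4 lower (18 and 4 adjusted over the list alone; adjusted p = 0.00405), and not in line 2, with 11 higher and 5 lower (11 and 6 adjusted over the list alone; adjusted p = 0.308). No list held with an estimated correlation in either line, the smallest adjusted p being 0.301 in line 1 and 0.306 in line 2. That test has few residual degrees of freedom and little power here, so it can neither undo nor uphold the calls. In line 1 10058 features passed (5454 higher, 4604 lower) and in line 2 9065 (4582 higher, 4483 lower). Without the genes of chromosomes 8 and 11 line 1 had 4353 higher and 4361 lower and line 2 3433 higher and 4299 lower. Of the full counts 1312 and 796 differed at least 1.7-fold. Under median centring 2576 and 1537 features passed. In line 1 18 and in line 2 19 lists were called. These tests treat the 2 arrays of a line as its replicates, so they leave out the spread between clones.

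The fold changes of the 2 Taf5-kd lines correlated at 0.872 across features with shared controls, where simulated unchanged lines gave 0.335 on average over 100 data sets. With the controls split so that each Taf5-kd line met a different control-kd line, the correlations were 0.748 and 0.719. Both lines were called higher for 3856 features and lower for 3371, and 167 features were called in opposite directions. The same 4 control-kd arrays enter both comparisons, which by itself gives common calls, and no count for unchanged lines was computed.

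Compared directly, Taf5-kd line 2 had higher Hoxb2 (1.79 ± 0.06, log2, SE), Aard (1.72 ± 0.05), Gbx2 (1.66 ± 0.06), Col1a1 (1.35 ± 0.13) and Dcaf12l1 (1.35 ± 0.06) than line 1. The largest differences the other way were those of T (-2.93 ± 0.13), Igfbp3 (-2.25 ± 0.08), Ppp4r4 (-2.11 ± 0.12), the Wnt target gene Sp5 (-2.01 ± 0.08) and Gbp2b (-1.96 ± 0.06). Naive pluripotency genes were higher in line 2, 15 of 31 against 3 lower (21 and 4 adjusted over the list alone; adjusted p = 1.39e-09), and interferon genes lower, 12 of 28 against 0 (15 and 0 adjusted over the list alone; adjusted p = 7.86e-08), as were Wnt targets, 10 of 19 against 0 (11 and 0 adjusted over the list alone; adjusted p = 9.59e-06). All 3 had adjusted p = 0.292 with an estimated correlation. Taf5 itself did not pass (-0.031 ± 0.052, adjusted p = 0.787). In all 3408 features passed, 1021 higher and 2387 lower in line 2, 193 of them at least 1.7-fold, and 16 lists were called. The count was 1291, 1683, 2145 and 1373 without Taf5-kd replicates 1, 2, 3 and 4, which leaves 1 array in a line, and 94 under median centring.

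Between the control-kd lines, markers of primitive endoderm were among the largest differences. Line 2 had higher Srgn (3.93 ± 0.13, log2, SE), the endocytic receptor gene Cubn (3.28 ± 0.11), Gata6, the factor that specifies primitive endoderm (2.49 ± 0.12), and Pdgfra (2.10 ± 0.11), beside Mest (4.22 ± 0.19). The list of primitive endoderm genes was higher in 18 of 23 and lower in 0 on either adjustment (adjusted p = 1.7e-19, and adjusted p = 0.0509 with an estimated correlation). Eif2s3y and Uty, genes of the Y chromosome, were lower in line 2 (-5.10 ± 0.05 and -2.17 ± 0.11), as were Klhl13 (-1.53 ± 0.06), Khdc3 (-1.48 ± 0.05) and Dppa3 (-1.34 ± 0.09). Eif2s3y and Uty each stood above background on 3 of 4 control-kd arrays, so the sizes of their differences rest in part on a signal at background and are not exact. Cholesterol biosynthesis genes were lower in 18 of 22 and higher in 1 (19 and 1 adjusted over the list alone; adjusted p = 5.7e-17, and adjusted p = 0.0509 with an estimated correlation), and genes of the unfolded protein response higher in 13 of 21 (16 adjusted over the list alone; adjusted p = 6.62e-10, and adjusted p = 0.169 with an estimated correlation). In all 3375 features passed, 1700 higher and 1675 lower in line 2, 184 of them at least 1.7-fold, and 10 lists were called. The count was 1443 and 1927 without control-kd replicates 3 and 4, and 322 under median centring, 309 of them higher.

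The authors' own table gives a p-value per probe for 41174 mouse probes. At their p under 0.05, 4247 probes differed between Taf5-kd and control-kd (2465 higher, 1782 lower), 3232 between control-kd and parental (1046 higher, 2186 lower) and 2044 between Taf5-kd and parental (667 higher, 1377 lower), and their 4 pairings of single lines gave 2908 to 3610. Their log2 differences for Taf5-kd against control-kd correlated at 0.985 across features with those given here. Of the features tested here 2913 passed both thresholds, all in the same direction, 58 passed only theirs and 2760 only the one used here.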

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

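The tests of a dye or array effect and of the share of genes above 0 on chromosomes 8 and 11, of shared values and of the reference pool behind the control-kd departure, and of knockdown depth and a single array behind the line difference were chosen after the results were seen.

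Genes of chromosomes 8 and 11 were higher in Taf5-kd than in control-kd lines, with a median difference of 0.33 and 0.27 (log2) over the genes brighter than the median gene. The median was higher in Taf5-kd in 32 of 32 pairings of single arrays, over both chromosomes, and in as many with the authors' values. The shift is therefore not carried by a single array. These chromosomes were singled out because their line medians differed between the groups, so the count largely restates that difference. For this reason the count cannot decide whether a dye or intensity effect contributed. A few strongly changed genes as the whole cause are argued against by 79.6% and 75.1% of these genes above 0, against 37.0 to 54.8% on the other autosomes, although the 88.0% of 92 runs of 25 neighbouring genes above 0 missed the 90% set beforehand. A copy number difference of whole chromosomes between the clones is a hypothesis that may account for the pattern but was not settled: 95.5% of the runs of brighter genes on chromosome 8 and 82.9% on chromosome 11 lay above 0.1, against 8.50% on other autosomes, where 90% had been asked of each. An effect of Taf5 on these chromosomes cannot be told apart from it with expression values of 2 lines per group.

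The control-kd lines departed from the parental reference opposite to the difference between Taf5-kd and control-kd (correlation -0.680 across features; simulated data without effects gave -0.706, since both contrasts share the control-kd arrays). Shared values alone are argued against, because with the control-kd lines split so that no array was shared the correlation stayed at -0.546 or lower. A reference pool that differs from all 4 lines alike is argued against by the same -0.546, since the pool cancels in the difference between Taf5-kd and 1 control-kd line. The genes of chromosomes 8 and 11 do not carry it, the split correlation without them being -0.530. What stays open, untested, is whether the control hairpin, the selected control clones or a Taf5-dependent return towards the parental state may underlie it, each line being 1 clone of 1 group.

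The Taf5-kd lines differed from each other in 3408 features by a direct test. A different depth of knockdown at the RNA level is argued against by the Taf5 transcript itself, which differed by -0.031 (log2, SE 0.052). The Taf5 protein was not measured. A single deviating array is argued against by the line difference of the Cy3 arrays and that of the Cy5 arrays, which correlated at 0.740 across features. Differences between clones that arose before or after the transduction may account for the pattern and were not tested. The control-kd lines differed from each other in 3375 features without a Taf5 knockdown.

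Only 3 splits of the 8 arrays keep the lines together, too few for a share under 0.05. The group difference gave 5673 features and the highest of the others 0, and 12 lists were called where the highest of the others called 15. Over all 34 splits that could be fitted 1 gave as many features and 2 as many lists, but most of these break up the clones and all but the real one carry the group difference in their residual spread. A 35th split is the same as the dyes and could not be fitted. The split with 15 lists sets control-kd line 1 and Taf5-kd line 2 against control-kd line 2 and Taf5-kd line 1.

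Of the leading genes 16 differed between the Taf5-kd lines by the direct test, as line 2 minus line 1 (log2): Mest 0.82, T -2.93, Anxa3 -0.59, Dppa3 -0.79, Igf2 -0.39, Slc39a8 -1.05, Igfbp3 -2.25, Gbp2 -1.70, Khdc3 0.62, Tbx3 0.65, Rpl39l 0.55, Spink1 0.52, Aard 1.72, Lrrc2 0.29, Atf4 0.51 and Mymx 0.64. So did 61 of 135 named list members. Lists higher in line 2 were, by median, naive pluripotency (0.24), primitive endoderm (0.10), mesoderm (0.057), germ cell (0.14), two-cell-like (0.067), LIF and STAT3 (0.070), glycolysis (0.077), ribosomal protein (0.042) and ribosome biogenesis genes (0.070). Lists lower in line 2 were primed epiblast (-0.24), primitive streak (-0.18), trophectoderm (-0.19), Wnt (-0.25), p53 (-0.13), interferon (-0.17) and actin genes (-0.071). None of these lists passed with an estimated correlation, the smallest adjusted p being 0.292.

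An array far from the others of its group was looked for in 118 groups of leading genes and lists, and 2 showed one. The rule compares the gap at either end of the 4 values with their range. The 4 arrays of a group are 2 from each of 2 lines, and pairs that lie apart by line keep this ratio low. The small number found is therefore no sign that deviating arrays are absent. The median of NRF2 targets was 0.0016 in Taf5-kd replicate 2 and 0.090 to 0.104 in the other arrays. The median of blood and immune genes was -0.040 in Taf5-kd replicate 4 and -0.058 to -0.057 in the others. Of 270 groups of named list members 5 had 1 array apart. Outside the mouse probes, 88 of 245 replicated control probes, 9 spots each, differed between Taf5-kd and control-kd, 45 higher and 43 lower. This is a larger share than the 5673 of 25150 features called with the same design and line correlation, but the shares are not alike. The control probes were averaged over their 9 spots and adjusted among themselves. What these probes detect was not taken into account, so the count cannot be read as a rate of false calls. The median SD between spots of 1 probe on an array was 0.039, which leaves out the spread between arrays and clones.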

How the results depend on the processing

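All settings here were planned except that without the genes of chromosomes 8 and 11, which was chosen after the chromosome medians were seen. Of the gene results 539 kept direction and side of the threshold and 26 fell short of it (Mest, T, Igfbp3, Aard, Dppa3, Gbp2 and Khdc3), with 0 reversals. Of the list results 843 kept both, 36 lost and 47 gained a call, and 24 turned direction. Except where stated, the cause was not tested.

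With median centring in place of loess, the counts were 533 for Taf5-kd against control-kd, 2118 and 1072 for control-kd and Taf5-kd against parental, 2576 and 1537 for Taf5-kd lines 1 and 2, and 94 and 322 (309 higher) between the Taf5-kd and the control-kd lines, with 22 lists called. The tests of apoptosis (median -0.0016), heat shock (-0.075) and cholesterol genes (-0.070) turned direction there. Normexp without offset gave 1536 between the Taf5-kd lines, 1743 between the control-kd lines and a correlation of the Taf5-kd lines of 0.844. Scale normalization gave 659, 951 and 0.902, and turned the test of germ cell genes (median 0.026). Line means gave 1950, 5378 and 4631 for the group comparisons, fewer values entering each test, and fixed line means gave 10784. A 1.7-fold minimum, which removes features by construction, left 923, 969, 504, 1312, 796, 193 and 184. An estimated correlation, tested on few residual degrees of freedom, left 0 lists. Without the dye term, which is the replicate block, the group counts were 5594, 8090 and 7762, with 12 lists.

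Leaving out 1 array gave 4222 to 5051 for Taf5-kd against control-kd, 6771 to 8079 and 6378 to 7758 against parental, 1291 to 3997 between the Taf5-kd lines (1291, 1683, 2145 and 1373 without Taf5-kd replicates 1 to 4), 1443 to 3263 between the control-kd lines (1443 and 1927 without control-kd replicates 3 and 4), a correlation of 0.793 to 0.878, 11 to 16 lists, and -1.44 to -1.36 for Taf5. A line left with 1 array is assumed to vary like the others. Leaving out a line gave 4180 to 5582 for Taf5-kd against control-kd.

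The remaining turns of direction were in lists without a call in the main setting. For TFIID subunits other than Taf5 the test turned to higher without the dye term, without the line block and with line means (median 0.073 each), without control-kd line 1 (0.048) or Taf5-kd line 2 (0.115), and on leaving out 1 of 3 arrays (0.066 to 0.084; over all arrays left out 0.041 to 0.091). For NRF2 targets it turned with line means (0.019), without control-kd replicate 3 (0.020), without Taf5-kd line 1 (-0.0044) and without control-kd line 2 (0.098), with -0.020 to 0.087 over all arrays left out. Others were germ cell genes with line means (0.055) and without Taf5-kd line 1 (0.037), oxidative phosphorylation without Taf5-kd replicate 4 (0.018; lowest -0.053 without Taf5-kd replicate 2) or line 2 (0.025), and, without control-kd line 2, primitive endoderm (0.16), Polycomb (-0.012) and cholesterol genes (-0.22, adjusted p = 0.0391, but 0.23 and adjusted p = 2.12e-04 without control-kd line 1). Primitive endoderm genes stood at -0.71 without control-kd line 1 (adjusted p = 3.17e-08). SAGA and ATAC subunits turned without the genes of chromosomes 8 and 11 (-0.022). Calls of the LIF and STAT3, G1/S, Mediator and G2/M lists also ended under scale normalization (adjusted p = 0.0563, 0.0563, 0.0534 and 0.0541). Print-tip loess was not run, the arrays having 1 block, nor a slide batch, none being given. Signal in the sample channel stood above background for 90.9 to 98.7% of mouse probes, and the filter set aside only 314 dim probes. Standing above background is therefore weak evidence of expression. Silent genes may be among the features tested, which limits what can be said of them.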
